A study of Homo sapiens with 6 samples.

How the data were processed

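The libraries were made from HepG2 RNA with a stranded mRNA kit from 500 ng of total RNA, per the labels' protocols. The deposited table holds whole-number raw counts per gene, which the authors made from their reads, for 3 control and 3 formononetin libraries. The submitters' processing notes name the GRCh38 genome, STAR 2.5.3a and StringTie 1.3.1c without saying what each did. The counter, its strand setting and the annotation are not given in the sources used here, so overlapping genes on either strand are treated as uncertain. Of 62729 rows, 60564 carry an Ensembl gene identifier and 2165 are loci of the kind that StringTie assembles and numbers itself (MSTRG), with no gene name. The latter held 3.82 to 5.62% of counts per library, name no gene and were left out of library sizes and tests, and keeping them was an added alternative. In every library the value 3 was more frequent than 2 (1701 to 1852 rows with 3 and 1586 to 1683 with 2), so 1 count may not be 1 independent read, and limits drawn from counts of 0 cover counting error only.

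Symbols came from a table of gene names that matched 60295 of the identifiers, and coordinates from GENCODE 29 (GRCh38), which holds 58457 of them. Libraries are named by group and replicate. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Counts of pairs within a group differed by a chi-square of 14.8 to 39.2 per degree of freedom, a measure that takes each count as 1 independent read. The correlation of log2 CPM was 0.982 to 0.985 within groups and 0.975 to 0.976 between them, across genes, which are not independent replicates. The labels name no batch, and no library was left out.

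Genes with too few counts were removed by filterByExpr, leaving 22230. Libraries were scaled with TMM, and formononetin was compared with control by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit, glmQLFTest, group as the only term, 3 against 3, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled library sizes, and the standard error is the log2 fold change divided by the square root of F. The biological coefficient of variation was 0.157. The test was tried on counts simulated from the real means and library sizes for 21744 genes of this comparison. It recovered 50 of 50 genes changed by 2 on the log2 scale, 40 of 50 by 1, 39 of 50 by -1 and 12 of 50 by 0.5. It called 7 of 21544 unchanged genes. The changed genes were drawn from those above a mean of 1 CPM and were far fewer than the 4596 called in the data, so recovery there may differ. Each simulated gene took its spread between libraries from the trend fitted over expression. Genes that vary more than this trend were thus not simulated, and recovery and false calls may be worse in the data.

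The design of each test, the gene lists and the alternatives were fixed before the data were examined. The 32 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, adjusted over the lists). On log2 values drawn independently for each gene, it called 1 of 1 shifted lists and 0 of 40 unshifted ones. Members that move together were not simulated, so this says nothing on the preset correlation. Lists were also tested with a correlation estimated per list and with fry. Named genes were the 6 largest rises and 6 largest falls with adjusted p under 0.05, a mean log2 CPM of 3 or more and complete separation of the groups. They also took up to 2 called members per list in its main direction and 1 in the other under the same expression limit, and 11 genes fixed in advance (AFP, ALB, CDKN1A, CDK1, CCNB1, MKI67, CCND1, MYC, DDIT3, CYP1A1 and 1 not reported here). Symbols that are clone, readthrough or pseudogene names were passed over, and some examples of lists are left out. CYP1A2, CD68, PECAM1 and the markers at 0 counts fall outside this rule and were named after their values were seen. Shares of counts and library totals were compared by exact permutation tests, two-sided. Alternatives were DESeq2 1.42.0, limma voom, other scalings (RLE, upper quartile, library total, centring on the median gene), other low-count filters, leaving out mitochondrial and the 10 largest genes, the replicate number as a block, and leaving out each library. Added after the data were seen were the assembled loci, summing genes whose exons overlap on the same strand by at least 50 bases, leaving out genes that span over 4-fold within a group, and adjustment of each library for GC content and exon length. Figures were drawn with matplotlib 3.10.9.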

Results

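RNA sequencing measured gene expression in 6 libraries of HepG2, an established human line from a liver tumour that keeps many functions of hepatocytes. The cells of 3 libraries had been given formononetin, a methoxylated isoflavone of clover, astragalus and other legumes, for 72 h at a labelled dose of 625 (the unit is written μm). The labels of the 3 control libraries name only culture medium and no solvent control. They also give no treatment time, so it is not known whether control cells were cultured as long. The series title presents formononetin as the active compound of a herb pair studied for liver cancer, and the comparison asks how transcript levels differ between cells with and without it. Counts on named genes were 30848848, 36243606 and 34606983 in control replicates 1 to 3 and 39052809, 37465148 and 45682722 in formononetin replicates 1 to 3. The totals were thus higher in all formononetin libraries (exact permutation p = 0.1, two-sided, the smallest value that 3 against 3 libraries allow). Values below are means ± SD over 3 libraries in CPM (counts scaled to a library total of 1000000), and log2 fold changes of formononetin against control ± their standard error.

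Formononetin libraries held far more transcript of several enzymes that oxidise and conjugate foreign compounds, led by CYP1A1 at 2.28 ± 0.399 CPM in control against 472 ± 19.1 CPM in formononetin libraries (n = 3). They also held more transcript of genes for DNA replication, recombination repair, the oxidative stress response and fatty acid metabolism. Median log2 fold changes were 0.91 for replication genes and 0.78 for targets of NRF2, a factor of the oxidative stress response. Secreted plasma protein genes were lower, with a median of -0.48, as were fetal liver and cytosolic ribosomal protein genes. None of these lists was called with an estimated correlation (adjusted p from 0.0762 to 0.199). Of 22230 genes tested, 2659 were raised and 1937 lowered, 4596 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small, with a median absolute log2 fold change of 0.46 among changed genes, and 585 reached 2-fold, 277 upwards and 308 downwards. The formononetin libraries all lay on the same side of the control libraries for 39.4% of tested genes, where chance gives 10%. The first principal component, with 38.9% of the variance, separated the groups, and control libraries ran from -38.3 to -35 on it against 36.1 to 37.1 for formononetin libraries. Control replicate 1 stood apart on the second component (16.5% of the variance), at 47.3 against -21.5 and -25.4 for the other controls. Its mean log2 CPM lay nearer to formononetin libraries for replication genes (4.74 against 4.46 and 4.44) and for mitosis genes (5.10 against 4.96 and 4.91). The split between directions depended on the scaling, with 1813 genes raised and 2737 lowered under upper quartile scaling. Leaving out 1 library lowered the counts most for formononetin replicate 3 (3049 genes changed, 1703 raised) and control replicate 3 (1272 lowered).

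Among genes with a mean log2 CPM of 3 or more, the largest rise was that of CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor (ENSG00000140465, chromosome 15, 74719542 to 74725610, GRCh38). It went from 2.28 ± 0.399 to 472 ± 19.1 CPM (n = 3 per group), a log2 fold change of 7.69 ± 0.12 with adjusted p = 4.32e-07. TXNIP, an inhibitor of thioredoxin that also limits glucose uptake (ENSG00000265972, chromosome 1, 145992435 to 145996600), was at 2.31 ± 0.0762 CPM in control and 40.8 ± 1.28 CPM in formononetin libraries, a change of 4.14 ± 0.08 (adjusted p = 9.90e-07). UGT1A1, which conjugates bilirubin (ENSG00000241635, chromosome 2, 233760248 to 233773299), was at 6.51 ± 1.09 CPM in control and 103 ± 9.09 CPM in formononetin libraries (3.99 ± 0.13, adjusted p = 1.16e-05). It shares its last exons with the other UGT1A genes, so the split of reads among them is uncertain, and the summed locus of 6 tested genes rose by 3.06 on the log2 scale. The aldehyde dehydrogenase gene ALDH3A1 (ENSG00000108602, chromosome 17, 19737984 to 19748943) changed by 3.86 ± 0.14 from 1.94 ± 0.37 to 28.1 ± 1.78 CPM, and a gene model overlaps it on the opposite strand. PTGR1, a prostaglandin reductase (ENSG00000106853, chromosome 9, 111549722 to 111599893), and AKR1B10, an aldo-keto reductase often raised in liver cancer (ENSG00000198074, chromosome 7, 134527592 to 134541408), changed by 2.40 ± 0.06 and 2.20 ± 0.05, with AKR1B10 at 97.8 ± 4.81 CPM in control and 450.4 ± 15.5 CPM in formononetin libraries. Adjusted p was 1.75e-05 for ALDH3A1, 4.59e-06 for PTGR1 and 3.22e-06 for AKR1B10.

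**Figure D1:**
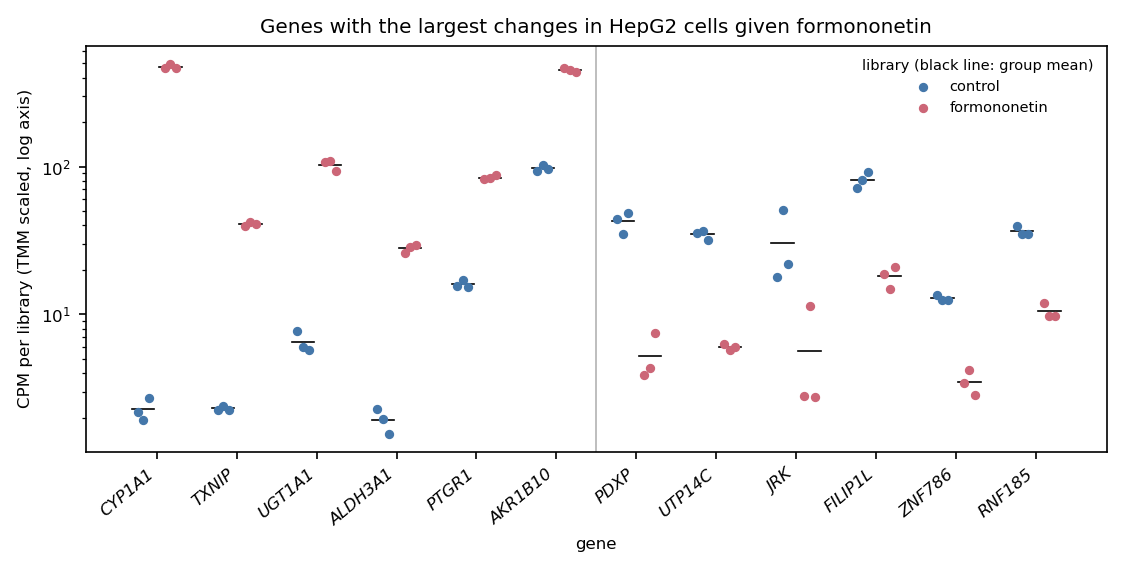
CPM of each library, on a log axis, for the 6 genes with the largest rise and the 6 with the largest fall, with 3 control libraries in blue, 3 formononetin libraries in red and group means as black lines. CYP1A1 stands at 2.28 CPM in control and 472 CPM in formononetin libraries on average, and JRK spreads widely within both groups.

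The largest fall was smaller than the 4 largest rises, and the first 2 falls belong to genes that share exons with a neighbour. PDXP, the pyridoxal phosphatase gene (ENSG00000241360, chromosome 22, 37658727 to 37666934), was at 42.7 ± 6.88 CPM in control and 5.26 ± 1.98 CPM in formononetin libraries, a log2 fold change of -3.02 ± 0.26 (adjusted p = 0.000487). It overlaps SH3BP1 and a further gene model on the same strand, and the 3 summed changed by 0.29 in the other direction (adjusted p = 0.0149, the highest of all alternatives, the lowest being 5.61e-39). UTP14C (ENSG00000253797, chromosome 13, 52024691 to 52033600), a gene copy for a ribosome assembly factor, changed by -2.52 ± 0.09 (adjusted p = 1.16e-05). Its sum with ALG11, which shares its exons, changed by -0.44 and was not called (adjusted p = 0.188, against 2.71e-104 to 0.00128 in the other alternatives). JRK (ENSG00000234616, chromosome 8, 142657460 to 142681968) was at 30.2 ± 17.9 CPM in control and 5.65 ± 4.94 CPM in formononetin libraries (-2.43 ± 0.64, adjusted p = 0.0358). The call of JRK was lost without control replicate 2 or 3 or formononetin replicate 1 or 3 (adjusted p up to 0.107) and in 1 of the other alternative settings. FILIP1L (ENSG00000168386, chromosome 3, 99830141 to 100114513) fell from 81.3 ± 10.5 to 18.1 ± 3.03 CPM (-2.17 ± 0.14, adjusted p = 0.000214). The zinc finger gene ZNF786 (ENSG00000197362, chromosome 7, 149069643 to 149090782) changed by -1.88 ± 0.15 and RNF185, a ubiquitin ligase gene (ENSG00000138942, chromosome 22, 31160183 to 31207019), by -1.80 ± 0.11, with adjusted p of 0.000437 and 0.000153.

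Among genes grouped by lists fixed before the data were examined, 25 of 27 targets of NRF2, the transcription factor of the oxidative stress response, rose and none fell, with a median log2 fold change of 0.78 (camera adjusted p = 1.08e-18; adjusted p = 0.0809 with an estimated correlation). AKR1B10 led them, followed by GCLM, a subunit of the enzyme that limits glutathione synthesis, at 22.4 ± 2.1 CPM in control and 67 ± 3.07 CPM in formononetin libraries (1.58 ± 0.08). Of 11 tested aryl hydrocarbon receptor targets, 6 rose and 1 fell (median 0.60, the same with CYP1A2 at the bound given next, camera adjusted p = 7.78e-05; adjusted p = 0.0809 with an estimated correlation). Among members with a mean log2 CPM of 3 or more, CYP1A1 and ALDH3A1 rose most. CYP1A2 had no counts in any control library and 1.36 ± 0.18 CPM in formononetin libraries, at least 15.3-fold above the level of 3 counts per control library. The member that fell was AHR, the receptor itself (-0.24 ± 0.06). The call of AHR was lost without control replicate 2 or 3 or formononetin replicate 2 or 3 (adjusted p up to 0.0892) and in 3 of the other alternative settings. Among drug metabolism genes 10 of 26 rose and 3 fell (median 0.36, camera adjusted p = 0.0467; adjusted p = 0.227 with an estimated correlation). This list call also ended without control replicate 3 or formononetin replicate 2 (adjusted p up to 0.102) and in 5 other settings. Lowered drug metabolism genes numbered 5 under upper quartile scaling or with a filter of 1 CPM in 3 libraries. Among those with a mean log2 CPM of 3 or more, the largest rise after UGT1A1 was in ABCG2, an efflux transporter (0.99 ± 0.09), and the largest fall in FMO5, a flavin monooxygenase (-0.68 ± 0.06). Adjusted over the list alone, 26 NRF2 targets were raised and 0 lowered, 7 receptor targets raised and 2 lowered, and 11 drug metabolism genes raised and 5 lowered.

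**Figure D2:**
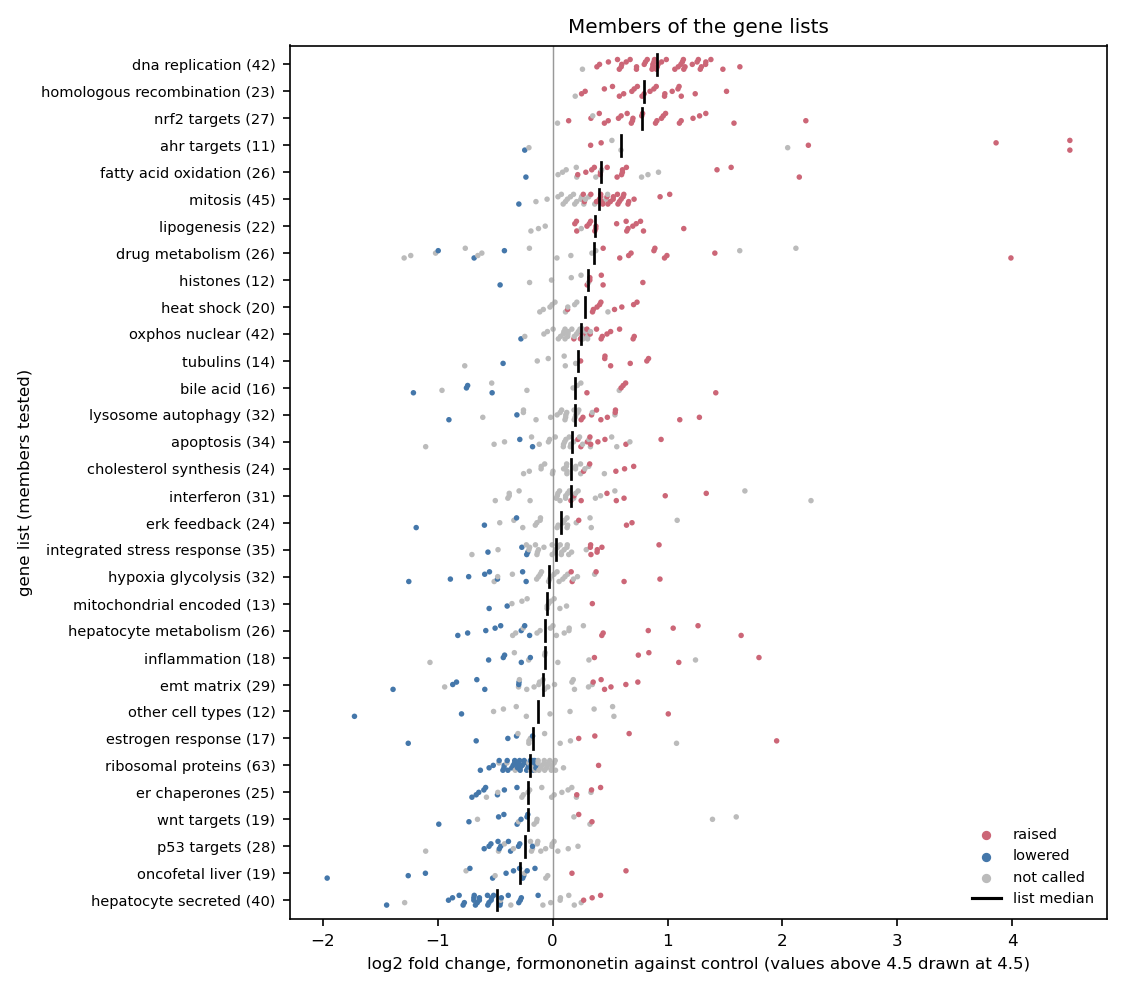
Log2 fold change of each tested member (points) and the median (black bar) of the 32 gene lists, ordered by median, with members raised in red, lowered in blue and not called in grey. CYP1A1 and CYP1A2 lie beyond the axis and are drawn at its limit. Medians run from -0.48 for secreted plasma proteins to 0.91 for DNA replication.

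Many cell cycle genes were higher with formononetin. Of 42 DNA replication and S-phase entry genes 41 rose and none fell, with a median of 0.91 (camera adjusted p = 1.38e-24; adjusted p = 0.166 with an estimated correlation). E2F2, a transcription factor of S-phase entry, was at 5.17 ± 1.4 CPM in control and 16 ± 0.859 CPM in formononetin libraries (1.63 ± 0.18). CDC6, which loads the replicative helicase, was at 23.8 ± 0.616 CPM in control and 66.4 ± 9.02 CPM in formononetin libraries (1.48 ± 0.10). Homologous recombination and Fanconi anaemia genes behaved alike, with 22 of 23 raised and a median of 0.80 (camera adjusted p = 6.79e-14; adjusted p = 0.129 with an estimated correlation). The nuclease gene EXO1 rose by 1.51 ± 0.15 and the polymerase gene POLQ by 1.12 ± 0.08. Among G2 and mitosis genes 25 of 45 rose and 1 fell, with a median of 0.41 (camera adjusted p = 7.36e-10; adjusted p = 0.227 with an estimated correlation). Raised mitosis genes numbered 14 without control replicate 2. MYBL2 rose most (1.02 ± 0.11) while ECT2, a factor of cell division, fell (-0.29 ± 0.06). CDK1, the mitotic kinase, changed by 0.71 ± 0.13 and its partner CCNB1 by 0.38 ± 0.08. The call of CCNB1 was lost without control replicate 2 or formononetin replicate 1 or 3 (adjusted p up to 0.0616). The proliferation marker MKI67 was called at adjusted p = 0.0479 (0.62 ± 0.18, 140.2 ± 8.63 against 215 ± 61.6 CPM). The call of MKI67 was lost without control replicate 1, 2 or 3 or formononetin replicate 1 (adjusted p up to 0.136) and in 6 of the other alternative settings. Its log2 fold change was 0.36 without formononetin replicate 3. CCND1 changed by 0.23 ± 0.04 (adjusted p = 0.00906) and by 0.15 under upper quartile scaling. MYC was not called (0.33 ± 0.19, adjusted p = 0.288), with a log2 fold change of 0.07 without formononetin replicate 3 and 0.50 without formononetin replicate 1.

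Replication-dependent histone genes had 6 of 12 members raised and 1 lowered (median 0.31, camera adjusted p = 0.0181; adjusted p = 0.422 with an estimated correlation). Raised histone genes numbered 3 under upper quartile scaling or without control replicate 2 or 3 or formononetin replicate 1 or 3. Tubulin genes had 7 of 14 raised and 1 lowered (median 0.22, camera adjusted p = 0.023; adjusted p = 0.227 with an estimated correlation), a call that ended in 1 other setting. Under upper quartile scaling the tubulin median was 0.14 and that of BCL2 family and caspase genes was 0.09. TUBG1, of the centrosome, changed by 0.84 ± 0.09, TUBB2B by -0.43 ± 0.05 and the histone gene H4C8 by 0.79 ± 0.11. Targets of p53 went the other way, with 11 of 28 lowered and none raised (median -0.24, camera adjusted p = 7.78e-05; adjusted p = 0.0809 with an estimated correlation). PLK2 fell by 0.59 ± 0.13 on the log2 scale and FBXO22 changed by -0.55 ± 0.08. The call of PLK2 was lost without control replicate 2 or 3 (adjusted p up to 0.0632). CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, was at 134 ± 10 CPM in control and 97 ± 53.3 CPM in formononetin libraries and was not called (-0.47 ± 0.42, adjusted p = 0.488). Formononetin replicate 3 was lowest, and the log2 fold change of CDKN1A was -0.08 without formononetin replicate 3 and -0.74 without formononetin replicate 2. In the list of BCL2 family, caspase and death receptor genes 9 of 34 rose and 2 fell (median 0.17, camera adjusted p = 0.023; adjusted p = 0.143 with an estimated correlation), a call that ended in 1 other setting. Raised members numbered 3 under upper quartile scaling, 4 with a replicate block or without control replicate 2 or 3 or formononetin replicate 3 and 5 without control replicate 1 or formononetin replicate 1 or 2. The largest rises with enough counts to be named were CASP2 (0.64 ± 0.16) and BAK1 (0.46 ± 0.07), which promotes apoptosis at mitochondria. BAX, of the same function, fell (-0.28 ± 0.05). The call of CASP2 was lost without control replicate 1, 2 or 3 or formononetin replicate 2 (adjusted p up to 0.103) and in 1 of the other alternative settings. Raised and lowered members, adjusted over the list alone, numbered 42 and 0 for replication, 22 and 0 for recombination, 32 and 2 for mitosis, 8 and 1 for histones, 7 and 2 for tubulins, 1 and 13 for p53 targets, and 10 and 2 for apoptosis.

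Both the synthesis and the oxidation of fatty acids had more transcript with formononetin. In the list for fatty acid and triglyceride synthesis 18 of 22 genes rose and none fell (median 0.37, camera adjusted p = 8.58e-08; adjusted p = 0.143 with an estimated correlation). SCD, the stearoyl-CoA desaturase, was at 1538 ± 122 CPM in control and 3392 ± 65.6 CPM in formononetin libraries (1.14 ± 0.06), and AGPAT2, which acylates lysophosphatidic acid, changed by 0.79 ± 0.15. Of 26 fatty acid oxidation and PPAR-alpha target genes 15 rose and 1 fell (median 0.42, camera adjusted p = 4.91e-09; adjusted p = 0.0762 with an estimated correlation). CPT1A, the enzyme that admits fatty acids to mitochondria, was at 155 ± 0.427 CPM in control and 419 ± 3.83 CPM in formononetin libraries (1.43 ± 0.03) and the transcription factor gene CREB3L3 changed by 1.55 ± 0.16. The coactivator gene PPARGC1A fell (-0.23 ± 0.06). The call of PPARGC1A was lost without control replicate 2 or 3 or formononetin replicate 1, 2 or 3 (adjusted p up to 0.0853) and in 3 of the other alternative settings. Sterol synthesis genes had 5 of 24 raised and none lowered (median 0.16, camera adjusted p = 0.0328; adjusted p = 0.6 with an estimated correlation). This list call also ended without control replicate 2 or 3 (adjusted p up to 0.171) and in 4 other settings. Raised sterol genes numbered 8 without control replicate 1. The sterol median was 0.08 under upper quartile scaling and 0.09 without control replicate 3. FDPS changed by 0.71 ± 0.09 and DHCR7 by 0.63 ± 0.11. Bile acid genes moved both ways, with 5 of 16 raised and 4 lowered, and the list was not called (median 0.20, mean -0.01, camera adjusted p = 0.57, direction up). Raised bile acid genes numbered 3 without control replicate 3. The bile acid median was 0.12 under upper quartile scaling and 0.13 without control replicate 2 or formononetin replicate 1. ACOX2, which shortens the bile acid side chain, changed by 0.64 ± 0.09 and NR1H4, the bile acid receptor FXR, by -0.74 ± 0.06. With p adjusted over the list alone, the raised and lowered members were 18 and 1 for lipid synthesis, 18 and 1 for oxidation, 5 and 0 for sterols, and 6 and 4 for bile acids.

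Of 40 genes for plasma proteins that hepatocytes secrete, 27 fell and 3 rose (median -0.48, camera adjusted p = 4.04e-09; adjusted p = 0.0866 with an estimated correlation). AHSG, which encodes fetuin-A, fell from 3675 ± 135 to 1962 ± 105 CPM (-0.91 ± 0.05) and the fibrinogen gene FGB changed by -0.81 ± 0.05, while SERPINC1, the antithrombin gene, rose (0.42 ± 0.07). ALB, the albumin gene, was at 7003 ± 237 CPM in control and 5102 ± 266 CPM in formononetin libraries (-0.46 ± 0.05, adjusted p = 0.00104). Fetal liver and progenitor genes were lower too, with 12 of 19 lowered and 2 raised (median -0.29, camera adjusted p = 7.78e-05; adjusted p = 0.0809 with an estimated correlation). AFP, the fetal plasma protein used as a serum marker of liver cancer, was at 2050.3 ± 52.1 CPM in control and 1549 ± 49.2 CPM in formononetin libraries (-0.40 ± 0.04, adjusted p = 0.000824). PROM1, a stem cell surface marker, changed by -1.11 ± 0.11 and PEG10 by -0.72 ± 0.06, whereas LIN28B, which blocks let-7 maturation, rose (0.64 ± 0.06). The list of urea cycle, gluconeogenesis and hepatocyte transcription factor genes was not called (camera adjusted p = 0.732), with 6 of 26 raised and 8 lowered. FAH, the last enzyme of tyrosine breakdown, rose by 1.64 ± 0.06, and the transcription factor gene ONECUT1 changed by -0.82 ± 0.06. Beta-catenin targets had 8 of 19 lowered and 2 raised (median -0.21, camera adjusted p = 0.0316; adjusted p = 0.352 with an estimated correlation). This list call also ended without control replicate 1 or 3 (adjusted p up to 0.0621) and in 1 other setting. The mean log2 fold change of beta-catenin targets was -0.05. Their mean log2 CPM overlapped between groups, at 5.845 to 5.968 in control and 5.805 to 5.917 in formononetin libraries. Lowered beta-catenin targets numbered 5 without control replicate 1 or 3 or formononetin replicate 3. DKK1 and LGR5 changed by -0.99 ± 0.07 and -0.73 ± 0.05, and TBX3 by 0.34 ± 0.04. Isoflavones can bind estrogen receptors, and of 17 estrogen-related genes 4 rose and 5 fell without a list call by camera (adjusted p = 0.539). By fry that list was called lower (adjusted p = 0.036). XBP1 and GREB1 changed by -0.66 ± 0.13 and -0.39 ± 0.05, and IGFBP4 by 0.37 ± 0.05. Members raised and lowered, adjusted over the list alone, numbered 5 and 27 for plasma proteins, 2 and 13 for fetal liver, 6 and 9 for hepatocyte metabolism, 3 and 10 for beta-catenin targets, and 4 and 7 for estrogen-related genes. For hepatocyte metabolism the median (-0.06) and the mean (0.05) differed in sign, as they did for estrogen-related genes (-0.17 and 0.04), and camera took the sign of the median in both. With counts thinned to the smallest library the median of estrogen-related genes was -0.09. Lowered estrogen-related genes numbered 3 with no low count filter or without formononetin replicate 1 or 2. Without formononetin replicate 2 or a low count filter, 4 of them were raised, more than were lowered.

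Among stress lists, 10 of 20 heat shock genes rose and none fell (median 0.28, camera adjusted p = 8.15e-05; adjusted p = 0.227 with an estimated correlation). HSPA1A and HSPA1B changed by 0.71 ± 0.06 and 0.73 ± 0.07, but these copies are nearly identical and their reads cannot be assigned with certainty. Endoplasmic reticulum chaperone genes were not called as a list, with 3 of 25 raised and 8 lowered (median -0.21, camera adjusted p = 0.245). The list was called lower without control replicate 1 (adjusted p = 0.00339), with 11 members lowered and a median of -0.34, against -0.13 without control replicate 2. Lowered chaperone genes numbered 2 without control replicate 3 or formononetin replicate 1 or 2, 3 without control replicate 2, 4 with no low count filter and 5 without formononetin replicate 3. Without control replicate 3, 3 were raised. SEL1L, of the degradation machinery, and the transcription factor gene XBP1 fell (-0.70 ± 0.11 and -0.66 ± 0.13). Amino acid response genes were not called either, with 7 of 35 raised and 4 lowered (median 0.03, camera adjusted p = 0.541). Lowered amino acid response genes numbered 1 without control replicate 2 and 2 under library total scaling, with no low count filter or without formononetin replicate 1, 2 or 3. PSAT1, of serine synthesis, changed by 0.43 ± 0.05 and the glycine transporter gene SLC6A9 by -0.56 ± 0.10. DDIT3, the stress factor CHOP, was at 15.1 ± 4.38 CPM in control and 10.9 ± 0.892 CPM in formononetin libraries without a call (-0.47 ± 0.20, adjusted p = 0.137), and its log2 fold change was -0.21 without control replicate 2. Lysosome and autophagy genes had 10 of 32 raised and 2 lowered (median 0.19, camera adjusted p = 0.00465; adjusted p = 0.129 with an estimated correlation). Lowered lysosome genes numbered 1 under library total scaling or without control replicate 3 and 4 under upper quartile scaling. GLA, a lysosomal galactosidase, changed by 1.28 ± 0.10, SQSTM1, the autophagy receptor p62 and itself an NRF2 target, by 1.11 ± 0.04, and TFEB, a regulator of lysosome genes, by -0.90 ± 0.09. Interferon-stimulated genes had 8 of 31 raised and none lowered (median 0.16, camera adjusted p = 0.00217; adjusted p = 0.0882 with an estimated correlation), led by OAS1 (1.34 ± 0.09) and OAS3 (0.98 ± 0.07), which sense double-stranded RNA. Raised interferon-stimulated genes numbered 4 without formononetin replicate 3 and 5 under upper quartile scaling, with a replicate block or without control replicate 3 or formononetin replicate 2. Upper quartile scaling also gave 2 lowered and medians of 0.08 for this list and 0.11 for lysosome genes. The raised and lowered members adjusted over the list alone were 11 and 0 for heat shock, 5 and 10 for chaperones, 7 and 5 for the amino acid response, 12 and 5 for lysosome genes, and 10 and 2 for interferon-stimulated genes.

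A further 4 lists moved both ways and were not called by camera. By fry the lists of glycolysis and hypoxia (adjusted p = 0.00338) and of matrix genes (adjusted p = 0.00538) were called lower. Glycolysis and hypoxia genes had 5 raised and 8 lowered of 32 (median -0.03, adjusted p = 0.284), and HK2, a hexokinase, was at 721 ± 29.2 CPM in control and 435 ± 23.8 CPM in formononetin libraries (-0.73 ± 0.05). Raised glycolysis and hypoxia genes numbered 2 without formononetin replicate 1, 2 or 3 and 3 under upper quartile scaling, with a replicate block or without control replicate 2 or 3. The mitophagy gene BNIP3L changed by -0.89 ± 0.08 and ADM by 0.93 ± 0.15. Matrix and epithelial-mesenchymal genes had 6 raised and 7 lowered of 29 (median -0.08, adjusted p = 0.288). Raised matrix genes numbered 2 without control replicate 2 or formononetin replicate 2 or 3 and 3 under upper quartile scaling or without control replicate 1 or 3. The actin-binding gene TAGLN changed by -1.39 ± 0.06, CCN1 by -0.87 ± 0.10 and TIMP1 by 0.64 ± 0.15. The call of TIMP1 was lost without control replicate 1 or 2 or formononetin replicate 2 or 3 (adjusted p up to 0.0772). Inflammation genes had 5 raised and 5 lowered of 18 (median -0.07, mean 0.16, adjusted p = 0.875, direction down), among them SAA4 (0.75 ± 0.11) and IL32 (0.36 ± 0.04), while RELB fell (-0.56 ± 0.11). The call of RELB was lost without control replicate 3 (adjusted p = 0.0522). The direction of that list was up without control replicate 1 or 2 or formononetin replicate 2 and with fry. Lowered inflammation genes numbered 3 under library total scaling, with no low count filter or without control replicate 1 or 2 or formononetin replicate 2 or 3. Growth factor response genes had 3 raised and 3 lowered of 24 (median 0.07, adjusted p = 0.784), among them the ephrin receptor gene EPHA2 (-0.59 ± 0.07), AREG (0.69 ± 0.15) and the ERK phosphatase gene DUSP6 (0.64 ± 0.15). The call of AREG was lost without control replicate 1 or 3 or formononetin replicate 1 or 3 (adjusted p up to 0.0622) and that of DUSP6 without control replicate 2 or 3 or formononetin replicate 1 or 3 (adjusted p up to 0.0762). Raised growth factor response genes numbered 1 without control replicate 3 or formononetin replicate 1 or 3 and 5 without control replicate 1. Lowered growth factor response genes numbered 5 under upper quartile scaling. Medians close to 0 changed sign under some settings for the lists of glycolysis and hypoxia (-0.11 to 0.01), growth factor response (-0.01 to 0.12), the amino acid response (-0.05 to 0.09) and hepatocyte metabolism (-0.14 to 0.01). Those of the matrix and inflammation lists ran from -0.16 to -0.04 and from -0.15 to -0.02. Adjusted over the list alone, the lists of glycolysis, matrix, inflammation and growth factor response in that order had 7, 6, 5 and 3 members raised and 9, 9, 6 and 3 lowered.

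Cytosolic ribosomal protein genes had 35 of 63 lowered and 1 raised, by small amounts (median -0.19, camera adjusted p = 3.25e-08; adjusted p = 0.199 with an estimated correlation). Lowered ribosomal protein genes numbered 21 without formononetin replicate 1 or 2, 22 without control replicate 3 and 23 with no low count filter, with a replicate block or without control replicate 2. RPS24 was at 345 ± 9.43 CPM in control and 235 ± 18.1 CPM in formononetin libraries (-0.55 ± 0.06) and RPL8 changed by -0.63 ± 0.13. The call of RPL8 was lost without control replicate 2 or formononetin replicate 2 (adjusted p up to 0.0519). RPS3 was the member that rose (0.40 ± 0.10). The call of RPS3 was lost without control replicate 1 or 2 or formononetin replicate 1 or 3 (adjusted p up to 0.0923) and in 1 of the other alternative settings. Many ribosomal protein genes have processed pseudogenes that can take their reads. Nuclear genes of the respiratory chain rose in 15 of 42 cases and fell in 1 (median 0.25, camera adjusted p = 4.44e-06; adjusted p = 0.0882 with an estimated correlation). Raised respiratory chain genes numbered 9 under upper quartile scaling. Lowered respiratory chain genes numbered 0 under library total scaling, with no low count filter, with a replicate block or without control replicate 1 or 2 or formononetin replicate 1, 2 or 3 and 3 under upper quartile scaling. ATP5MC1, of ATP synthase, changed by 0.70 ± 0.08. Of 13 genes of the mitochondrial genome 1 rose and 2 fell without a list call (camera adjusted p = 0.288, direction down). That list was called lower without formononetin replicate 3 (adjusted p = 0.0142) and its direction was up without formononetin replicate 1 (adjusted p = 0.892). Its median of -0.05 ran from -0.15 to 0.05 over the alternatives. Lowered mitochondrial genes numbered 1 without control replicate 1, 2 or 3 or formononetin replicate 2 and 4 without formononetin replicate 3. MT-CO1 was at 16796 ± 256 CPM in control and 11460.0 ± 1128 CPM in formononetin libraries (-0.55 ± 0.07), and MT-CYB changed by -0.39 ± 0.09. The call of MT-CYB was lost without control replicate 1, 2 or 3 or formononetin replicate 2 (adjusted p up to 0.0614). MT-ND6, which lies on the other strand, rose (0.35 ± 0.06). Mitochondrially encoded genes took 3.83 ± 0.0643% of counts in control and 3.21 ± 0.381% in formononetin libraries (exact permutation p = 0.1, two-sided, the smallest possible). The 10 genes with the most counts, among them APOB, FN1 and the small RNA genes RN7SL1 and RN7SK, took 13.9 ± 0.576% and 10.9 ± 0.969% (exact permutation p = 0.1). When adjusted over the list alone, 2 ribosomal protein genes were raised and 41 lowered, against 20 and 2 nuclear respiratory genes and 1 and 2 mitochondrial ones.

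Markers of blood, endothelial, fibroblast and stellate cells, fixed as a check for other cells, were mostly at low counts, and 12 of 27 could be tested. The endothelial marker PECAM1 was an exception, with 732 to 1215 counts per library, or 28.3 CPM at most. PTPRC, COL1A2, COL3A1 and DCN had 0 counts in all 6 libraries, which allows up to 3 counts per library. Of the 12 tested 1 rose and 2 fell, with 1 and 2 when adjusted over the list alone. The list was not called by camera (adjusted p = 0.541) and was called lower by fry (adjusted p = 0.012). Its median of -0.12 changed sign over the alternatives (-0.26 to 0.14). PDGFRB was at 13.3 ± 1.11 CPM in control and 4.04 ± 0.361 CPM in formononetin libraries (-1.72 ± 0.12). ACTA2, smooth muscle actin, was at 65.5 ± 1.92 CPM in control and 37.9 ± 1.75 CPM in formononetin libraries (-0.79 ± 0.06). The marker that rose was CD68 (1.01 ± 0.23), a lysosomal protein of macrophages, at 7.93 CPM at most. None of the 21 list calls held with a correlation estimated for each list, for which the lowest adjusted p was 0.0762. Without adjustment 8 lists were higher and 3 lower at p under 0.05 on that basis. Lists above with no member falling, or for p53 targets rising, had at most 2 such members at an unadjusted edgeR p under 0.05, at most 1 by DESeq2 and 0 by limma voom.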

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

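All tests in this part were chosen after the results they concern were seen. Signal in loci outside the comparison called for a closer look: of 2099 assembled loci with no gene name that had enough counts, 95 were raised and 312 lowered with formononetin when tested together with the named genes. MSTRG.8644 rose most among those of at least 3 log2 CPM, from 80.2 ± 28.4 to 438 ± 72.5 CPM (2.45 ± 0.28, edgeR adjusted p = 0.00144), and MSTRG.9209 fell most (-1.77 ± 0.10). Their positions are not known here.

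The fall of PDXP and UTP14C was weighed against counts moved between overlapping gene models. The PDXP locus, summed over the overlapping genes on the same strand, changed by 0.29 where PDXP changed by -3.02, so a move of counts between models may account for its fall. UTP14C lost 28.7 CPM while ALG11 gained 11.4 CPM, a log2 fold change of 0.44 ± 0.25 where 0.93 would take up the whole loss, so moved counts and a real fall cannot be told apart there at this spread. For JRK, FILIP1L, ZNF786 and RNF185 the same explanation stays open, since 0 of these 4 has a tested partner on the same strand and the places of the assembled loci are not known here. Such moves also occur without regard to treatment: RN7SL2, a gene of the signal recognition particle RNA, differed 3.61-fold between libraries, but its sum with the assembled locus MSTRG.4565 differed only 1.37-fold, which fits counts moved between a named gene and an assembled locus. A real change in transcript use was not tested.

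The median of the DNA replication list was 0.83 or more under all 4 other scalings. A scaling moves all genes alike, and those run put the median of all tested genes only between -0.09 and 0.032. They thus could not have removed the rise. For the same reason no scaling can set the list, at 0.91, apart from the median tested gene, at -0.011. Scaling therefore does not account for that gap. A scaling error common to all settings, which would shift both values, was not tested. The list median was 0.91 with all libraries thinned to the smallest total, but random thinning leaves expected ratios between libraries unchanged. Thinning therefore cannot decide whether library depth plays a part. Adjusted for GC content and gene length the list median was 0.88, against 0.92 on the same scale before. A bias of either kind thus does not account for the rise. An effect of formononetin on the cell cycle stays a hypothesis that these values do not test. A difference in cell density, or an effect of a solvent that the control labels do not name, would follow the groups in the same way and was not tested.

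The fall of plasma protein genes was weighed against scaling between libraries, against a few genes taking most of the counts and against a uniform loss of hepatocyte transcripts. The list median stayed at -0.44 or lower under the 4 other scalings. Those scalings move all genes alike and by too little to remove the fall whatever its cause. No scaling can set the list, at -0.48, apart from the median tested gene, at -0.011, so scaling does not account for that gap. An error common to all scalings, which would shift both values, was not tested. The second needs a larger share of counts for the 10 largest genes. Their share differed by -2.98 percentage points and was lower in every formononetin library. These genes include APOB and TF of this list, so the share is not independent of the fall and cannot decide on the second. A uniform loss would lower the hepatocyte metabolism list as well. Its median was -0.06, against -0.48 for plasma protein genes, which argues against such a loss. In that list 6 of 26 members rose and 8 fell. The raised members alone do not decide, since 2659 of all 22230 tested genes rose. A selective effect of formononetin on these genes stays a hypothesis, with cell density and an unnamed solvent untested.

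The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Only the real split gave 4596 changed genes, 1 of 10, and the highest of the other splits gave 5. For gene lists called by camera with a preset correlation, the real split gave 21 and the highest other 16, with 1 split as large. Each other split has libraries of both groups on each side, so the difference between groups widens the spread within its sides. Part of that difference also remains between the sides, with a replication list median of up to 0.44 in absolute value, against 0.92. The 5 genes and 16 lists are therefore not levels that chance alone would give.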

How the results depend on the processing

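The genes changed numbered 3638 to 4866 over the settings that keep all libraries and the group-only model, which covers the count model, scaling, filters and the alternatives of summed loci and of widely spanning genes, added after the data were seen. With the assembled loci kept, also added then, 5000 named genes and unnamed loci together changed. No gene called both in the comparison and in an alternative changed sign, except 2 with summed loci. PDXP reversed there, at 0.29 as a summed locus. With 1 library left out, fewer samples gave 3049 to 3667 changed genes, 1703 to 2189 raised and 1272 to 1478 lowered, lowest without formononetin replicate 3 for the first counts and without control replicate 3 for genes lowered. Of 102 named genes, 81 kept their direction and side of the threshold in every setting run, and among 1935 values 85 lost a call, 1 gained one and 1 reversed. Lists raised and lowered numbered 0 and 0 with an estimated correlation, which allows for members moving together, and fry, which tests whether a list's own genes move, gave 15 lists higher and 9 lower, against 16 and 5 by camera with the preset correlation. The cause of each single change was not tested. Of 21 called lists, 16 kept their call in all but the estimated correlation among the 16 alternatives run for list tests.

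Replicate numbers did not pair the samples: deviations from the group means correlated at -0.002, 0.009 and -0.022 for same-numbered libraries, and not every library correlated best with its own number. With the replicate number as a block 3283 genes changed (1921 raised, 1362 lowered). In counts simulated at this depth 50 of 50 changes of 2 on the log2 scale were recovered and 12 of 50 changes of 0.5. How far depth sets this limit was not tested. The simulation changed far fewer genes than were called in the data and gave every gene the spread of the fitted trend, so recovery there may differ.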

Other observations

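In this part the carbohydrate-response test was written before its result was seen, and the other tests and genes were chosen after. Among 166 families of genes that share a symbol root, the PSMD and PSMB families of proteasome genes were higher with formononetin. Of these 10 of 14 PSMD genes of the regulatory particle rose and none fell (median 0.39, camera adjusted p = 3.87e-05; adjusted p = 0.394 with an estimated correlation). So did 6 of 10 PSMB genes of the catalytic core (median 0.35, adjusted p = 0.00124; adjusted p = 0.394 with an estimated correlation). PSMD2 was at 152 ± 5.9 CPM in control and 242 ± 4.65 CPM in formononetin libraries (0.67 ± 0.04) and PSMB3 changed by 0.59 ± 0.05. Nucleoporin genes rose in 16 of 23 cases and fell in none (median 0.30, adjusted p = 3.87e-05; adjusted p = 0.394 with an estimated correlation), led by NUP155 (0.62 ± 0.05). Raised nucleoporin genes numbered 10 without control replicate 3 or formononetin replicate 1 or 3. Aldehyde dehydrogenase genes rose in 11 of 17 cases and fell in 1 (median 0.48, adjusted p = 0.000699; adjusted p = 0.394 with an estimated correlation). Collagen genes were lower, with 9 of 22 lowered and none raised (median -0.21, adjusted p = 0.0149; adjusted p = 0.567 with an estimated correlation), COL4A5 at 113 ± 6.29 CPM in control and 66.2 ± 3.84 CPM in formononetin libraries (-0.77 ± 0.06). With a filter of 1 CPM in 3 libraries the collagen median was -0.40 over 15 genes. Under each scaling run these families kept the sign of their median, and the counts of 0 above were also 0 at an unadjusted edgeR p under 0.05, by DESeq2 and by limma voom. With an estimated correlation no family was called.

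All 6 tested metallothionein genes, which bind zinc and copper, rose, with a median log2 fold change of 1.48 and at least 1.40 under each other scaling. MT1A among them had few counts, at 0.219 ± 0.2 CPM in control and 1.11 ± 0.274 CPM in formononetin libraries, and was close to the threshold (edgeR adjusted p = 0.0475). MT1E was at 23.4 ± 1.57 CPM in control and 66.8 ± 4.76 CPM in formononetin libraries (1.51 ± 0.08, edgeR adjusted p = 8.75e-05) and MT1G changed by 1.73 ± 0.18. These genes are close copies of each other, so the split of reads among them is uncertain.

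The rise of TXNIP, a gene that carbohydrate-response factors switch on, may reflect carbohydrate-response transcription. ARRDC4, PKLR and KLF10, other genes of that response, had been seen to rise by 1.82 ± 0.19, 1.06 ± 0.17 and 0.76 ± 0.06. Of 5 more genes fixed for the test (RGS16, TKFC, TM6SF2, FGF21 and KHK), 3 had enough counts, and 2 of these rose. TKFC was at 53.8 ± 7.83 CPM in control and 113 ± 2.25 CPM in formononetin libraries (1.07 ± 0.10) and KHK changed by 0.63 ± 0.06, while TM6SF2 was not called (0.30 ± 0.22, edgeR adjusted p = 0.407). The bound set beforehand, 3 raised genes, was not met, and too few genes were testable to decide. MLXIPL, which encodes the carbohydrate-response factor ChREBP, was not called (-0.19 ± 0.07, adjusted p = 0.0858).

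Replication genes rose more than mitosis genes. The mean log2 CPM of the replication list minus that of the mitosis list was -0.44 ± 0.07 in control and 0.13 ± 0.02 in formononetin libraries, a difference of 0.57 (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest possible). A larger share of S-phase transcripts against mitotic transcripts may lie behind this, but the design cannot pass the threshold, and a shift in the share of cells in S phase cannot be told apart from more transcript per cell.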
